A study of Lactococcus lactis with 2 samples.

How the data were processed

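Total RNA of 2 Lactococcus lactis F44 cultures, one labelled as overexpressing ythA and one with the empty plasmid, was isolated with a column kit, treated with DNase I and made into standard Illumina libraries, per the labels' protocols. Reads were converted with bcl2fastq 2.16, per the submitters' processing notes. The aligner, the counting tool, the genome build, the strandedness and the treatment of reads that match more than 1 gene are not given in the sources used here. Reads shared between near-identical genes, such as transposases and prophage genes, could have been split or dropped, and values of such genes are uncertain.

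The authors deposited 2 tables, one of 1955 genes and a filtered one of 735 genes that are all in the first. Per the file headers each row holds a gene ID, a length, a count and an RPKM value (reads scaled to gene length and library total) for each library, a log2 ratio, a p-value and a false discovery rate, followed by KEGG, gene ontology and protein descriptions. The deposited counts are whole reads per gene and are not normalized. The deposited RPKM values equal the count times 1000000000 divided by the length and the column total, with a largest difference of 4.75e-05. The deposited log2 ratio equals the log2 of the RPKM ratio with an RPKM of 0 set to 0.001. The authors' p-value was made with 1 library per group, and the test behind it is not given in the sources used here. It was exactly 0 for 349 genes, among them genes with an absolute log2 ratio as small as 0.07, and 75.4% of all genes had a false discovery rate of at most 0.001, so it was used only as one alternative filter. The filtered table is exactly the set of genes with an absolute log2 ratio of at least 1 and a false discovery rate of at most 0.001. All 1955 lengths are multiples of 3 and are called coding lengths. The gene IDs run from 1 to 2212 with 257 numbers that have no row, and genes behind those numbers were not analysed here.

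The columns were assigned to the libraries by their names. The deposited counts were scaled to the total of all gene counts per library, and the log2 ratio was taken with 0.5 added to each count. A ratio of the counts was given with its exact conditional (Clopper-Pearson) 95% interval. The median count per gene was 1118 in the library labelled as overexpressing and 621 in the control, so intervals are narrow for most genes, but reads without molecular identifiers are not independent molecules, and the spread between cultures is unknown. A count of 0 was given the upper limit of 3 counts. The 20 most counted genes took 28.9% of the counts in the library labelled as overexpressing and 41.7% in the control.

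Counts of differing genes used a floor of 50 counts in the higher library and a ratio of 2. The genes named are the PspC-family genes, the 12 highest and 12 lowest log2 ratios among genes past that floor with a description other than hypothetical, up to 2 undescribed genes per direction, and up to 4 members per gene list with the largest absolute log2 ratio. Lists of at most 11 members could be given in full. These rules, the symbols and words of the 43 gene lists and the alternatives were fixed before the data were examined. ythA was to be found by symbol, or failing that by a PspC description, and never by its values.

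List members were found by symbol or by fixed words in the protein description or in the first KEGG name with an e-value of at most 1e-20. The lists as fixed applied the words to protein descriptions of genes without a symbol. Their use on KEGG names, and on genes with a symbol outside the list, went beyond that. A KEGG name at that limit existed for 1353 genes. The words also caught genes of other functions, and 72 such matches were removed by hand after the values had been seen; the lists without this removal are one of the alternatives. The list for plasmid replication and resistance and the list for ribosomal and non-coding RNA had 0 members after that removal, so signs of RNA quality were not measured. A list's median over members with at least 10 counts in the higher library was set against the medians of 10000 random lists of the same size, matched in 20 bins of mean expression, and against random lists made of runs of neighbouring genes. A percentile of 2.5 or 97.5 marks a list as standing apart, as a description of these 2 libraries and not as a test across cultures.

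Symbols were looked up by protein accession in a reference gene table of the assembly ASM317683v1 of another strain, in which 46 of the 1955 genes had a match and 15 a symbol. No reference genome and no coordinates of F44 were used here, so positions are given only as the order of the gene IDs.

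Alternatives were the floors of 10 and 200 counts and no floor, TMM scaling (edgeR 4.0.16 in R 4.3.3), a median log2 ratio of 0, totals without the 20 most counted genes and ythA (all 3 PspC genes were left out, since ythA itself is not named), a pseudocount of 5, the deposited RPKM with a pseudocount of 1, the near bound of the interval as the threshold, a 4-fold threshold, and the authors' false discovery rate together with the ratio. Totals without the glyceraldehyde 3-phosphate dehydrogenase gene, the glycolysis list without it and the nisin list with DYH_g0568 were added after the data had been seen. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

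The procedure was tested on simulated data, Poisson counts for the same 1955 genes and library sizes with 200 genes changed. These draws held counting error alone, with no spread between cultures and no shift shared by most genes. They check the calculation and cannot tell how many of the differing genes would differ again in other cultures. In this simulation of the overexpression comparison, 100 of 100 genes changed 3-fold and 100 of 100 changed 8-fold were recovered in the right direction, and 0 of 1755 unchanged genes passed. The 95% intervals held the true ratio for 95.6% of 1870 genes with an expected count of at least 10, and 12 of 200 random lists lay outside percentiles 2.5 to 97.5.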

Results

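RNA was sequenced from 2 cultures of Lactococcus lactis F44, a strain of a lactic acid bacterium used in dairy fermentation whose gene table includes the genes for the lantibiotic nisin. One culture carried a plasmid for overexpression of ythA, which the series title calls a transcriptional regulator, and the other carried the empty plasmid. Both were grown in seed medium and sampled at mid-log phase. There was 1 library per group, so the difference has no replicate check, no test across cultures was made and no p-value was computed. The library labelled as overexpressing held 8733391 counts and the library labelled as control 8319649 counts, over 1955 listed genes. Of these genes, 4 had a count of 0 in the first library and 17 in the second. A count of 0 allows up to 0.344 CPM (normalised counts, scaled to the library total) in the library labelled as overexpressing and up to 0.361 CPM in the control. Ratios are given as the library labelled as overexpressing over the library labelled as control, with the exact 95% interval of a ratio of counts in parentheses. Those intervals, and the limits for a count of 0, cover counting error only.

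The comparison addresses which transcripts differ when ythA is overexpressed, and the targeted gene comes first because it checks the labels. The gene table names no gene ythA. It describes 3 neighbouring genes as PspC-family stress-responsive regulators, the family to which YthA belongs, and does not say which of them is ythA. DYH_g1877, with a coding length of 465 bases, had 27323 counts in the control and 39010 in the library labelled as overexpressing, a ratio of 1.36 (1.34 to 1.38). DYH_g1878, with a coding length of 204 bases, had 10006 counts in the control and 7650 in the other library, a ratio of 0.728 (0.707 to 0.750). DYH_g1876, the shortest of them, had 100 and 57 counts in the same order, a ratio of 0.543 (0.385 to 0.759). None of the 3 reached a 2-fold excess in the library labelled as overexpressing, so the counts do not bear out its label, and every direction given here is a direction between the libraries as labelled. With the median gene set to no change, DYH_g1877 also had a negative log2 ratio, -0.21.

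Most genes had a higher share of the counts in the library labelled as overexpressing. The median log2 ratio of all 1955 genes was 0.63 when each library was scaled to its total count. Log2 ratios between 0 and about 0.6 are therefore positive by total count and negative with TMM scaling or with the median gene set to no change. Among 1751 genes with at least 50 counts in the higher library, 618 were at least 2-fold higher and 103 at least 2-fold lower in the library labelled as overexpressing, which makes 85.7% of the differing genes higher. This split depended on the scaling. It was 233 higher and 259 lower (47.4% higher) with TMM scaling, and 212 higher and 276 lower (43.4% higher) with the median log2 ratio set to 0. With the 20 most counted genes and the PspC genes left out of the totals it was 389 higher and 175 lower (69.0% higher).

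Genes of arginine synthesis stood at the top of the ranking. Argininosuccinate synthase (DYH_g0089), which joins citrulline to aspartate, had 31 counts in the control and 12862 in the library labelled as overexpressing, a ratio of 395 (278 to 582). Argininosuccinate lyase (DYH_g0090), which releases arginine in the next step, went from 76 to 16256 counts, a ratio of 204 (163 to 259). Acetylornithine deacetylase (DYH_g0459) was 10.9-fold higher (10.3 to 11.7), and the ArgB protein (DYH_g0714) 6.28-fold higher (4.43 to 9.14). Of the 7 measured arginine synthesis genes, 6 were at least 2-fold higher and none was at least 2-fold lower. Their median log2 ratio was 2.63, which is 2.00 above the median of all genes. Of 10000 random gene lists of the same size and expression level, 0 had a median as high, and of 10000 built from runs of neighbouring genes 14 did. Under TMM scaling all 7 kept a positive log2 ratio, with a median of 2.02, and 6 were still at least 2-fold higher.

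Transport genes for glutamate or arginine were among the same top genes. The ATP-binding protein of a glutamate ABC transporter (DYH_g1720) had 15 counts in the control and 1263 in the library labelled as overexpressing, a ratio of 80.2 (48.4 to 144). The substrate-binding protein of a glutamate or arginine ABC transporter (DYH_g0458) had 621 and 7806 counts, a log2 ratio of 3.58. The arginine deiminase pathway, which breaks arginine down to ornithine, ammonia and carbon dioxide with formation of ATP, was also higher. Arginine deiminase (DYH_g2005) had a log2 ratio of 2.01, ornithine carbamoyltransferase (DYH_g2004) one of 2.25, and the carbamate kinases DYH_g2001, DYH_g2002 and DYH_g1613 had log2 ratios of 2.27, 2.70 and 1.05. A further ornithine carbamoyltransferase (DYH_g0715, log2 ratio 2.55) is listed next to ArgB and was counted here because of its description. All 6 members were at least 2-fold higher, their median log2 ratio of 2.26 lay 1.63 above that of all genes, and 4 of 10000 matched random lists and 9 of 10000 lists of neighbouring genes had a median as high. With TMM scaling 5 of the 6 were still at least 2-fold higher.

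**Figure D1:**
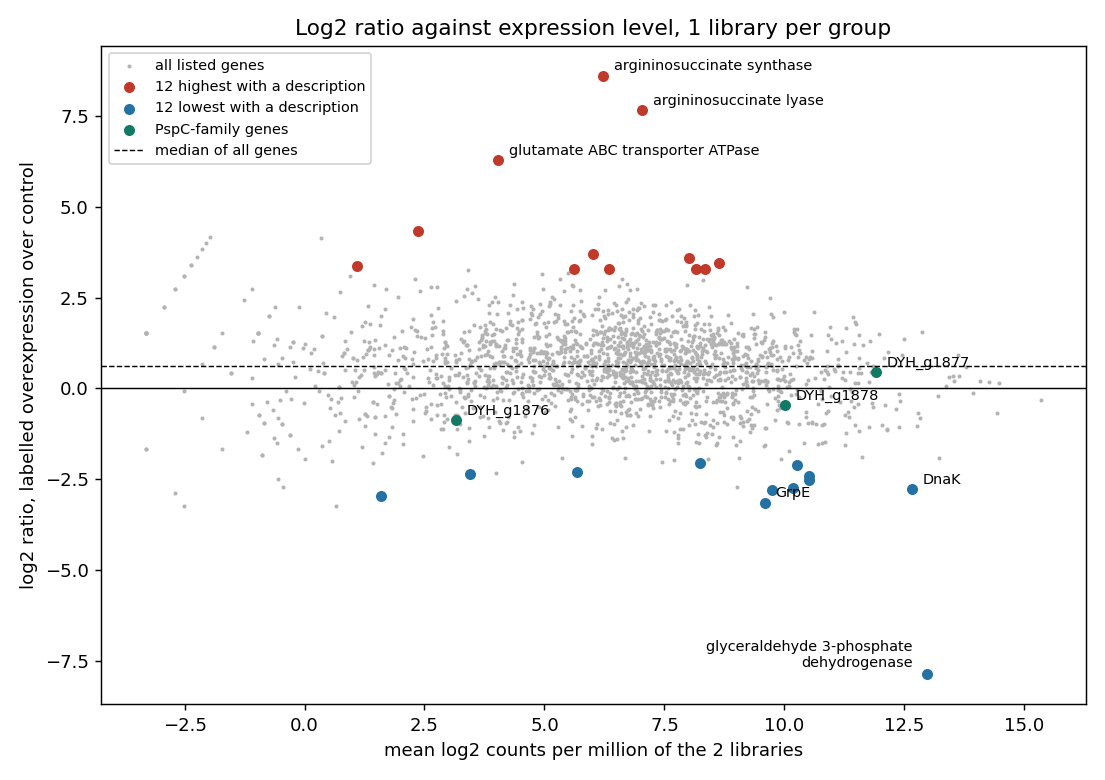
Each point is 1 of the 1955 genes, with the mean log2 CPM of the 2 libraries on the x axis and the log2 ratio of the library labelled as overexpressing over the control on the y axis. The dashed line at 0.63 is the median of all genes, argininosuccinate synthase lies highest at 8.60, glyceraldehyde 3-phosphate dehydrogenase lies lowest at -7.87, and the 3 PspC-family genes lie between -0.88 and 0.44.

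Pyrimidine synthesis and uptake genes were higher as a group. Carbamoyl-phosphate synthase small subunit (DYH_g1529) and aspartate carbamoyltransferase (DYH_g1530), the enzymes of the first steps of the pathway, were both 9.82-fold higher, with intervals of 9.16 to 10.6 and 9.11 to 10.6. Orotate phosphoribosyltransferase (DYH_g0987) was 9.87-fold higher (8.58 to 11.4). A phosphoribosyl transferase (DYH_g1533) listed beside this cluster had 9 and 202 counts, a log2 ratio of 4.34. Of 12 measured members, 11 were at least 2-fold higher and none at least 2-fold lower. The group's median log2 ratio was 2.94, or 2.31 above all genes, and 2.32 with TMM scaling, where 10 members were still at least 2-fold higher, and 0 random lists of either kind had a median as high. Purine genes did not stand apart, with a median log2 ratio of 0.48 over the 5 measured of 9 members, at percentile 29.3. Adenylosuccinate synthetase (DYH_g1914) was the only measured one at least 2-fold higher, with a log2 ratio of 1.63. The unmeasured members had fewer than 10 counts in both libraries, so this list samples purine synthesis only in part.

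The shikimate pathway, which leads to the aromatic amino acids, differed in the same direction. Shikimate kinase (DYH_g1663) had a log2 ratio of 2.52, 3-dehydroquinate synthase (DYH_g1677) of 2.40, 3-dehydroquinate dehydratase (DYH_g1576) of 2.37 and prephenate dehydratase (DYH_g1662) of 2.33. Of the 10 measured tryptophan and shikimate genes, 8 were at least 2-fold higher, with a median log2 ratio of 2.02, which 1 of 10000 matched random lists and 2 of 10000 lists of neighbouring genes reached. With TMM scaling 7 of them were at least 2-fold higher. In the aspartate family, diaminopimelate decarboxylase (DYH_g1205, 2.32), homoserine dehydrogenase (DYH_g1077, 2.29) and homoserine kinase (DYH_g1078, 2.09) were more than 4-fold higher, and 5 of 11 measured members were at least 2-fold higher, or 4 with TMM scaling. That list's median of 0.94 stood at percentile 79.7. Histidine synthesis had a median log2 ratio of 1.23 with 6 of 7 members at least 2-fold higher, led by histidinol-phosphate aminotransferase (DYH_g1126) at 1.67, and stood at percentile 89.7. With TMM scaling the median was 0.61 and 1 of the 7 was at least 2-fold higher. Branched-chain amino acid synthesis had none of 9 measured members at least 2-fold apart by total count, and a median of 0.31 at percentile 18.5. With TMM scaling 1 of the 9 was at least 2-fold lower, and the median became -0.30.

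Nisin genes were higher apart from the first ones of the cluster. The nisin A precursor gene (DYH_g0566), with 179539 counts in the control and 209390 in the other library, had a log2 ratio of 0.15, and nisB (DYH_g0567), for a modification enzyme, had 0.35. Both values turn negative with TMM scaling or with the median gene set to no change. The NisC protein gene (DYH_g0569) had a log2 ratio of 1.35, the immunity protein gene (DYH_g0570) 1.46, the leader peptidase gene (DYH_g0571) 1.47 and the sensor gene nisK (DYH_g0573) 1.70. The response regulator gene between them (DYH_g0572) had 5866 and 17469 counts, a ratio of 2.84 (2.75 to 2.92). The 3 transporter genes that close the list, DYH_g0574, DYH_g0575 and DYH_g0576, had log2 ratios of 1.30, 1.77 and 2.11. The words fixed for the list missed DYH_g0568, which lies between nisB and NisC, has the KEGG name NisT and had a log2 ratio of 0.99. Of the 10 listed nisin genes, 8 were at least 2-fold higher by total count, and 3 were with TMM scaling; with DYH_g0568 it was 8 and 3 of 11. The median of 1.47 was reached by 0 of 10000 matched random lists and by 530 of 10000 lists of neighbouring genes, and stood at percentile 94.7 of the latter. With DYH_g0568 the median was 1.46, reached by 1 of 10000 matched random lists and at percentile 93.2 of lists of neighbouring genes.

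**Figure D2:**
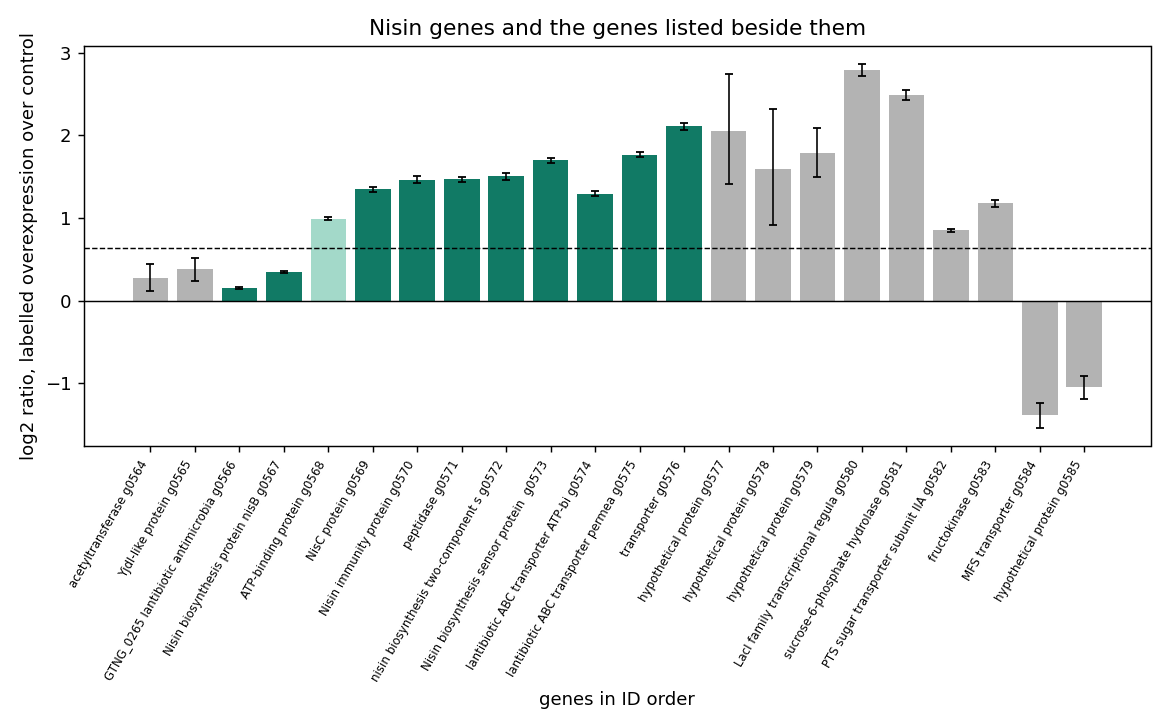
Bars show the log2 ratio of the library labelled as overexpressing over the control for 22 genes in ID order, with exact 95% counting intervals, the 10 listed nisin genes in green, DYH_g0568 with the KEGG name NisT in pale green and other genes in grey; the dashed line is the median of all genes. Within the cluster the ratio is lowest at 0.15 for the nisin precursor and highest at 2.11 for DYH_g0576, and lies at 2.79 for the LacI-family regulator DYH_g0580 beyond the cluster.

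Cell envelope genes differed by group. In peptidoglycan precursor synthesis, 10 of 18 measured members were at least 2-fold higher and none at least 2-fold lower, with UDP pyrophosphate phosphatase (DYH_g2153) at a log2 ratio of 1.99 and N-acetylglucosamine-1-phosphate uridyltransferase (DYH_g1823) at 1.74. The median of 1.14, 0.50 above all genes, stood at percentile 98.0, and at 96.9 of lists of neighbouring genes. In wall polysaccharide and teichoic acid synthesis, 11 of 13 members were at least 2-fold higher, led by a family 2 glycosyltransferase (DYH_g0116, 2.87) and a polysaccharide biosynthesis protein (DYH_g0119, 2.30), with a median of 1.25 at percentile 96.0. Fatty acid synthesis had 11 of 16 members at least 2-fold higher, led by a phosphopantetheinyl transferase (DYH_g0752, 1.55) and a hydroxymyristoyl-ACP dehydratase (DYH_g0690, 1.48), and a median of 1.17 at percentile 98.8, or 92.6 of lists of neighbouring genes. With TMM scaling 3 precursor genes, 3 polysaccharide genes and 0 fatty acid genes were at least 2-fold higher. The 3 polysaccharide genes were DYH_g0110, DYH_g0116 and DYH_g0119, which all lie in the run from DYH_g0108 to DYH_g0120 described further below.

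The medians of other envelope groups lay inside percentiles 2.5 to 97.5 of random lists. Penicillin-binding and wall assembly proteins had a median log2 ratio of 0.71 over 11 members at percentile 63.6, from penicillin-binding protein 2B (DYH_g0308) at -0.93 to FtsW (DYH_g0547) at 1.30. Cell division genes had 0.89 over 16 members at percentile 92.0, with FtsX (DYH_g0951) at 1.78. Peptidoglycan hydrolases had -0.05 over 6 members at percentile 6.66, with N-acetylmuramidase (DYH_g0435) at 1.08 and a muramidase (DYH_g1305) at -0.76. The 2 listed genes for D-alanylation of teichoic acids, DYH_g1182 and DYH_g1180, had log2 ratios of 0.93 and 0.23. Phospholipid synthesis had a median of 0.81 over 6 members at percentile 61.0. The 6 genes listed for envelope stress outside the PspC family had a median of 0.21 at percentile 16.2 and went both ways. They ranged from DYH_g1250 at -1.45, with 147 counts in the control and 56 in the other library, to DYH_g0441 at 1.89. Both are described as arsenate reductases, but their KEGG name is the regulatory protein Spx, by which they were listed. DYH_g1238 and DYH_g0554, with log2 ratios of -0.99 and 0.66, have the same KEGG name. The median of this list therefore mostly describes Spx-like genes and not the envelope stress response as a whole.

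Heat shock chaperones were lower in the library labelled as overexpressing. GrpE (DYH_g0931) was 8.81-fold higher in the control (8.43 to 9.20), DnaK (DYH_g0932), the chaperone that GrpE serves, 6.87-fold higher there (6.77 to 6.97), the repressor HrcA (DYH_g0930) 5.35-fold (5.20 to 5.51) and GroES (DYH_g0362) 4.28-fold (4.15 to 4.42). Of 15 measured chaperone and protease genes, 7 were at least 2-fold lower and 3 at least 2-fold higher in the library labelled as overexpressing. Their median log2 ratio of -0.97 lay 1.61 below that of all genes and 0 random lists of either kind had a median as low. With TMM scaling 10 were at least 2-fold lower and 0 at least 2-fold higher.

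A run of neighbouring genes with transport and envelope descriptions was lower by a similar amount. The ATP-binding protein of an ABC transporter described as a cobalt transporter (DYH_g1611) was 6.96-fold higher in the control (6.69 to 7.24), the transcriptional attenuator of the LytR family (DYH_g1610) 6.67-fold (6.45 to 6.90), the ABC transporter permease (DYH_g1612) 5.75-fold (5.59 to 5.93), and the gene of no known function beside them (DYH_g1609) had a log2 ratio of -2.70. Other genes with the lowest ratios were a transcription regulator (DYH_g1345, -2.96, from 70 to 9 counts), a rhodanese-like protein (DYH_g0698, -2.35), a response regulator of the LytTR family (DYH_g1992, -2.29) and the carbon starvation protein CstA (DYH_g0378, -2.06).

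The lowest ratio of any gene belonged to glyceraldehyde 3-phosphate dehydrogenase (DYH_g0455), a central enzyme of glycolysis. It held 12.3% of all counts in the control, 1020083 counts, and 0.0526% in the library labelled as overexpressing, 4590 counts, a 233-fold higher share in the control (227 to 240). Over all 17 measured glycolytic genes the median log2 ratio was 0.20, at percentile 24.3 of matched random lists and 8.54 of lists of neighbouring genes, and became -0.42 with TMM scaling. Among the 16 others, 4 were at least 2-fold higher and 3 at least 2-fold lower, or 2 and 4 with TMM scaling. Their median log2 ratio was 0.29, at percentile 37.7 and 14.5 of the same kinds of list, and became -0.32 with TMM scaling. Glucose-6-phosphate isomerase (DYH_g2130) had a log2 ratio of 1.96, a phosphoglycerate mutase (DYH_g1661) 1.82 and glucokinase (DYH_g1994) -1.91. DYH_g1661 is only a probable phosphoglycerate mutase by its KEGG name. It had 148 counts in the control and 550 in the other library, and is listed next to prephenate dehydratase (DYH_g1662). In pyruvate and mixed-acid metabolism, acetate kinase (DYH_g1984, 1.84) and formate acetyltransferase (DYH_g0543, 1.24) were more than 2-fold higher by total count, and the list's median of 0.63 over 7 members stood at percentile 77.8. The 7 held 3 genes at least 2-fold higher and 0 at least 2-fold lower. With TMM scaling it was 1 and 1, without formate acetyltransferase among the higher, and the median was 0.014.

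Also among the 12 highest ratios was an RNA methyltransferase (DYH_g1066), with 5 counts in the control and 59 in the other library, a log2 ratio of 3.37. The manganese ABC transporter genes DYH_g1241, DYH_g1242 and DYH_g1243 had log2 ratios of 3.71, 3.29 and 2.70. The metal ion list as a whole stood low, with a median of 0.12 over 23 members at percentile 1.89, or 4.50 of lists of neighbouring genes, and the median became -0.50 with TMM scaling. Of the 23, 6 were at least 2-fold higher and 3 at least 2-fold lower, with a cation transporter (DYH_g1700) lowest at -1.97; with TMM scaling it was 3 higher and 7 lower. Peptide uptake genes and peptidases had 9 of 18 members at least 2-fold higher, led by the dipeptidase PepV (DYH_g0751, 2.05), and a median of 1.13 at percentile 99.8, or 94.1 of lists of neighbouring genes. With TMM scaling 3 of the 18 were at least 2-fold higher and 1 at least 2-fold lower. Among lactose, galactose and sucrose genes, the LacI-family regulator DYH_g0580 (2.79) and sucrose-6-phosphate hydrolase (DYH_g0581, 2.49) were highest, 5 of 9 members were at least 2-fold higher (3 with TMM scaling), and the median of 1.18 stood at percentile 94.8.

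Ribosomal protein genes had a median log2 ratio of 0.24 over 53 members, 0.39 below the median of all genes and at percentile 1.06 of matched random lists, or 4.49 of lists of neighbouring genes. The sign of that median turned with TMM scaling, to -0.37. Of the 53, 9 were at least 2-fold higher, such as L33 (DYH_g2075, 2.85), and 4 at least 2-fold lower, such as L35 (DYH_g1775, -1.49). With TMM scaling 2 were at least 2-fold higher and 9 at least 2-fold lower. Aminoacyl-tRNA synthetases had a median of 0.67 over 24 members at percentile 68.6, with cysteinyl-tRNA synthetase (DYH_g1785) highest at 2.13. RNA polymerase genes had a median of 0.21 over 7 members at percentile 24.4. The 8 listed F0F1 ATP synthase genes lay between -0.51 and 0.66, with a median of 0.07 at percentile 22.1 and a median of -0.55 with TMM scaling. Prophage genes, whose reads can be shared between copies and whose values are uncertain for that reason, had a median of -0.43 over 13 measured members at percentile 0.61, with a phage capsid protein (DYH_g1312) at -1.16.

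**Figure D3:**
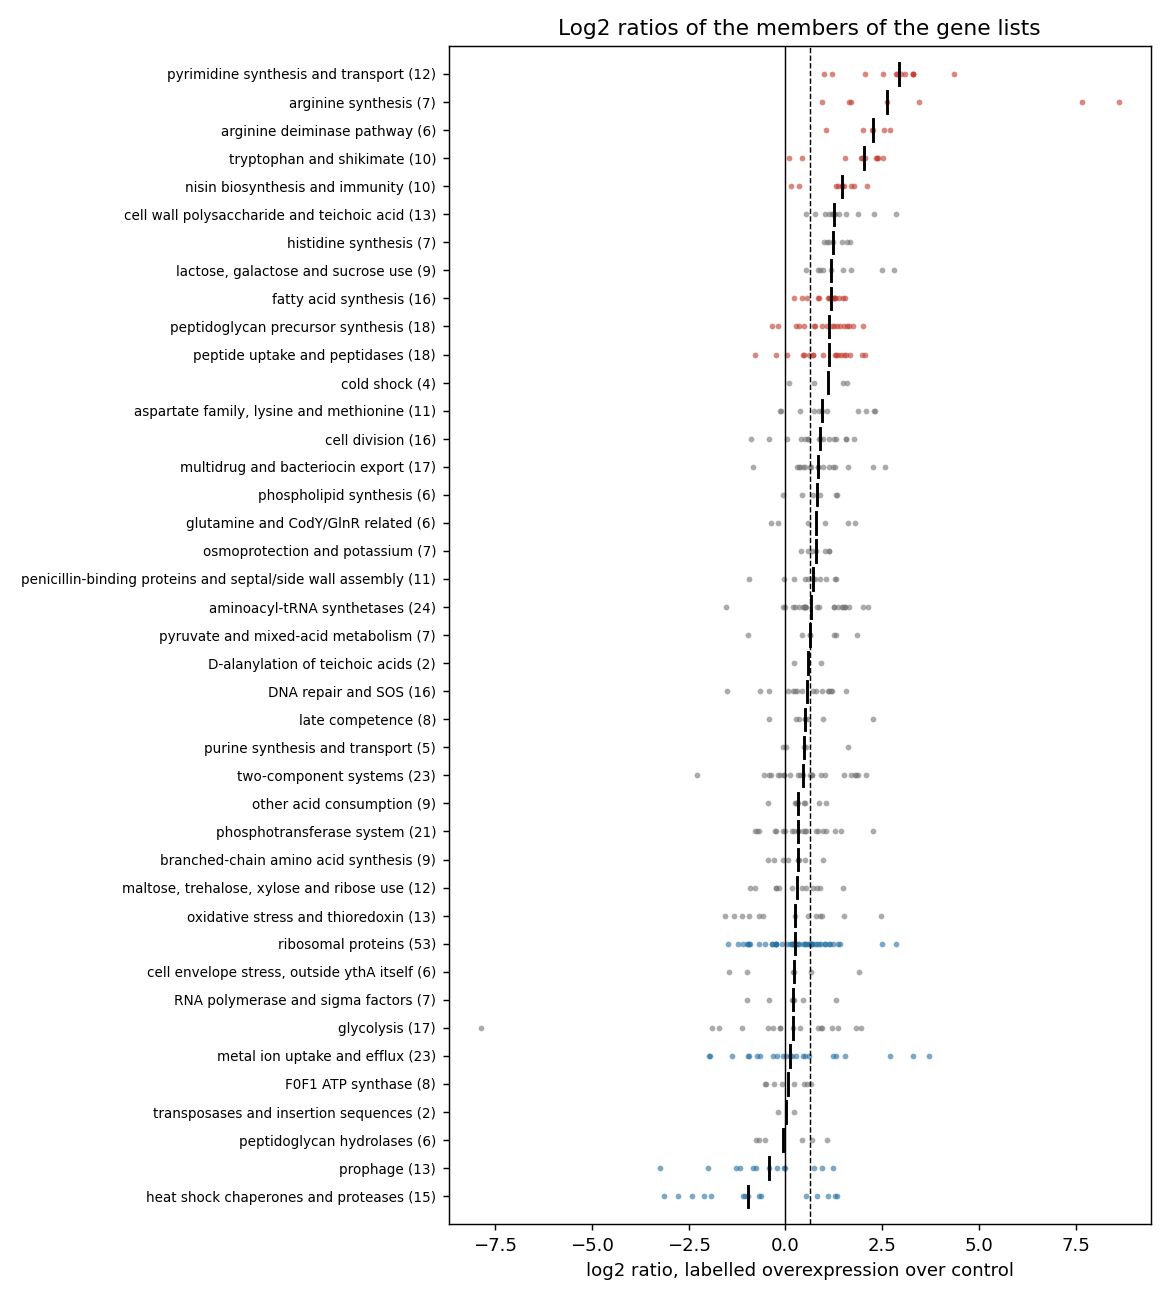
Each point is the log2 ratio of the library labelled as overexpressing over the control for 1 measured gene, in 41 gene lists sorted by their median (black bar), with the number of measured members in brackets and the median of all genes as a dashed line. Lists whose median lies at or above percentile 97.5 of 10000 matched random lists are red (8 lists) and those at or below percentile 2.5 are blue (4 lists); pyrimidine synthesis has the highest median at 2.94 and heat shock the lowest at -0.97.

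Across the 41 lists with at least 2 measured members, 8 medians lay at or above percentile 97.5 and 4 at or below percentile 2.5 of matched random lists, where about 2.05 lists in all would lie outside by chance. Against random lists of neighbouring genes, which keep the tendency of adjacent genes to move together, 4 and 2 did. The remaining lists lay between these percentiles. Of the 38 medians above 0 by total count, 17 lay below 0 with TMM scaling, and no median turned the other way. Cold shock genes had a median of 1.11 (percentile 87.4), osmoprotection and potassium 0.78 (72.3), multidrug and bacteriocin export 0.83 (70.3), glutamine and nitrogen regulation 0.80 (71.8) and late competence 0.50 (46.7). DNA repair had 0.57 (50.4), sensor and regulator pairs 0.46 (31.4), other acid-consuming enzymes 0.33 (24.2), oxidative stress and thioredoxin 0.26 (23.4), the phosphotransferase system 0.32 (22.9) and maltose, trehalose, xylose and ribose use 0.31 (16.9). The 2 transposases, uncertain for the same reason as the prophage genes, had log2 ratios of 0.23 and -0.19.

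The authors' deposited table gives its own ratios and p-values for the same 2 libraries, and these compare the libraries, not the conditions. In the filtered part of the authors' deposited table, 735 genes were kept as differing, 625 higher and 110 lower, by the rule of an absolute log2 ratio of at least 1 and a false discovery rate of at most 0.001. For DYH_g1877 the authors' deposited table lists a log2 ratio of 0.44, for DYH_g1878 one of -0.46 and for DYH_g1876 one of -0.88, and none of these genes is in its filtered part. For argininosuccinate synthase (DYH_g0089) it lists 8.63 and for glyceraldehyde 3-phosphate dehydrogenase (DYH_g0455) it lists -7.87.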

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

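No paired analysis was possible because each group has 1 library and no replicate numbers pair them. The median log2 ratio of all genes was 0.63 as reported, 0.016 with TMM scaling, -0.024 with the median of genes past the floor set to 0, 0.32 without the 20 most counted genes and the PspC genes in the totals, and 0.44 without the glyceraldehyde 3-phosphate dehydrogenase gene, an alternative chosen after seeing the data. The 618 genes at least 2-fold higher became 233, 212, 389 and 481 under these 4 scalings, and the 103 genes at least 2-fold lower became 259, 276, 175 and 148. A 4-fold threshold left 123 higher and 16 lower, as its construction requires. The other floors, the other pseudocount, the RPKM values, the interval bound and the authors' false discovery rate kept both counts within 1.5 times, from 483 to 683 higher and from 77 to 132 lower. DYH_g1876 had a log2 ratio of -1.49 with TMM scaling and -1.53 with the median set to 0. DYH_g1877 had -0.17, -0.21, 0.13 and 0.26 in the order of the scalings above, and DYH_g1878 had -1.07, -1.11, -0.77 and -0.65. Of 41 list medians, 38 lay above 0 as reported, and 17, 18, 9 and 3 of these turned below 0 under the 4 scalings. Among lists that stood apart, the medians of ribosomal proteins turned from 0.24 to -0.37, -0.41 and -0.066 under the first 3 scalings, and those of metal ion genes from 0.12 to -0.50, -0.54, -0.19 and -0.069 under all 4. A scaling adds one constant to every log2 ratio, which is the cause of these turns, and it moves no percentile of a list. Against runs of neighbouring genes, 4 lists in place of 8 stood above percentile 97.5 and 2 in place of 4 below percentile 2.5. With members of at least 50 counts, 7 stood above and 3 below. With members matched by symbol alone, 9 lists kept at least 2 members, of which 1 stood above and 1 below. Without the removal of word matches, chosen after seeing the data, 9 stood above and 3 below. Also chosen after seeing the data, the nisin list with DYH_g0568 had a median of 1.46 and the glycolysis list without DYH_g0455 one of 0.29. Depth limits the genes with few counts, such as DYH_g1876 with 100 and 57, and the single library per group limits all of them.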

Other observations

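All sets in the first 2 paragraphs were chosen after their values were seen, and so were the tests of the 3 patterns below, except the one on the most counted genes. Of 6 universal stress protein genes, 5 were at least 2-fold lower in the library labelled as overexpressing. DYH_g0051, DYH_g0868, DYH_g1300, DYH_g1765 and DYH_g1793 had log2 ratios of -1.51, -1.50, -1.47, -1.07 and -1.57, and DYH_g2211 had 0.65. In the run from DYH_g1503 to DYH_g1508, 5 of 6 genes were at least 2-fold lower. DYH_g1506 and DYH_g1507, described as surface proteins with a WxL domain, had log2 ratios of -1.11 and -1.26, the 3 genes described as hypothetical, DYH_g1504, DYH_g1505 and DYH_g1508, had -1.57, -1.29 and -1.50, and the surface anchor protein DYH_g1503 had -0.08. Beyond the chaperones named by rule, GroEL (DYH_g0363) had a log2 ratio of -1.91, DnaJ (DYH_g2198) -1.10 and ClpE (DYH_g0452) -1.03, while the protease FtsH (DYH_g0020) had 1.29 and trigger factor (DYH_g0446) 1.34.

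A run of 13 genes from DYH_g0108 to DYH_g0120, with polysaccharide synthesis and tyrosine kinase descriptions, was at least 2-fold higher throughout. The log2 ratios went from 1.09 to 3.01 with a median of 1.93, and with TMM scaling 10 of the 13 were at least 2-fold higher. DYH_g0110, DYH_g0116, DYH_g0119 and DYH_g0120 are also members of the wall polysaccharide list above, so the run and that list are not separate results. The Fe-S cluster assembly genes DYH_g1715, DYH_g1716 and DYH_g1717 had log2 ratios of 1.26, 1.27 and 1.23, and with TMM scaling 0 of these 3 were at least 2-fold higher. Among genes with polyketide synthesis descriptions, the acyl-CoA transferase (DYH_g1101) had 15292 counts in the control and 37418 in the other library, a log2 ratio of 1.22, and was not 2-fold higher with TMM scaling. DYH_g1102, DYH_g1103 and the hybrid nonribosomal peptide synthetase (DYH_g1106) had log2 ratios of 0.35, 0.07 and -0.12, and the regulator DYH_g0728 had 0.39. Genes with consecutive IDs had similar ratios. Across 1568 such pairs the Spearman rho of their log2 ratios was 0.55, against at most 0.07 in 1000 shuffles; this is across genes, which are not independent replicates.

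None of the 3 PspC-family genes was at least 2-fold higher in the library labelled as overexpressing. The highest log2 ratio of any of them under any setting was 0.44, that of DYH_g1877 by total count. Every alternative scaling lowered all log2 ratios, so these scalings could not have uncovered a rise hidden by the total count. With a pseudocount of 5 DYH_g1877 stayed at 0.44, but its counts are too high for a pseudocount to matter. Exchanged libraries would need one of the PspC-family genes to be at least 2-fold higher in the library labelled as control. The largest such ratio was 1.84 (1.32 to 2.60) for DYH_g1876, whose interval reaches past 2, and with TMM scaling DYH_g1876 and DYH_g1878 had log2 ratios of -1.49 and -1.07, so an exchange cannot be told apart from correct labels for these genes. It also stays open whether the plasmid copy of ythA has a row in the gene table.

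The glyceraldehyde 3-phosphate dehydrogenase gene (DYH_g0455) had a log2 ratio of -7.87. Reads moved to another listed gene are argued against, since it lost 1066220 reads at equal depth while the largest gain of any other gene was 74336 (DYH_g0313), 6.97% of the loss. Scaling is argued against too, as its largest shift was 0.66. So is loss of a region on both sides of the gene, as the lowest log2 ratio of its 2 neighbours past the floor was -1.51. These neighbours, DYH_g0456 and DYH_g0457, lie on the same side. On the other side DYH_g0454, with 44 counts in the control and 18 in the other library, was below the floor. Its log2 ratio was -1.34, and a loss reaching to that side alone was not tested. Reads moved to genes without a row, and a fault of this gene's counting in one library, stay open, because the counts carry no positions. The overexpression of ythA named by the design also stays open, as untested.

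Most genes had a higher share of counts in the library labelled as overexpressing, with a median log2 ratio of 0.63. Split by mean expression into 10 groups, genes past the floor had medians from 0.95 in group 3 to 0.21 in group 10, the most expressed. An even background of genomic DNA is argued against: the 196 genes lowest in the control had a median of 2.44 RPKM in the other library, where an even background of the size of the median gain would need 29.9 RPKM. The test on the most counted genes, whose bounds were set before its result was seen, left a median of 0.32 without them (0.26 to 0.38 over resampled genes, an interval added after the result was seen), 50.9% of the shift. This lies above the 0.1 that a full account by these genes would give. The bound set beforehand against them was 0.5 of the shift, which 50.9% only just met. The later interval reaches below that bound, but it treats genes as independent and covers no spread between cultures. Part of the shift goes with the most counted genes, as the median of 0.63 became 0.32 without them. That part follows from the arithmetic of shares, in which genes that lose share raise the share of the others. Shares cannot tell whether the most counted genes fell or the other genes rose, and the rest of the shift stays open.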
